A study of Arabidopsis thaliana with 12 samples.

How the data were processed

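The deposited table holds 1 column per sample for 12 samples of total RNA from Arabidopsis thaliana ecotype Columbia, 6 taken 2 days after mildew infection and 6 without infection, and 3439 probes numbered between 1 and 4607. Group and replicate number were taken from the sample titles. The values are intensities on a linear scale in the deposited table, as judged from the values themselves, which are never negative, are skewed, have column means near 1 and stop at 100. The background correction, scaling, lower limit and ceiling that made them, the scanner and whether samples shared an array are not given in the sources used here. The direction and linear scale follow from the values, while the scaling stays unknown.

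The log2 medians of the columns differed by up to 1.30, more than the 0.1 set as the limit for a table that is already normalized, so the columns were quantile normalized, raised to a floor of 0.00277 (the 1st percentile of positive values) and taken to log2. Probes tied at 0 take the mean quantile of their ranks, so that a 0 stands higher in a column with more zeros. Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, 2-sided), with mildew against no mildew and no block, and p-values were adjusted by the Benjamini-Hochberg method over 3439 probes with a threshold of 0.05. A fold is 2 to the power of the difference between mean log2 values, and for dim probes it depends on the floor. This design, 25 gene lists and the alternatives named below as set out beforehand were fixed before the data were examined.

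Gene names came from the platform annotation, updated through Entrez identifiers and a RefSeq gene table of assembly TAIR10.1. Of the probes, 692 had 1 gene, 870 had several and 1877 were not listed, and 690 of the 692 were matched, to 689 genes. Probes with several genes were left unnamed. The build behind the probes is not given in the sources used here, so no coordinates are printed. AT2G25870 alone had more than 1 probe, with log2 differences of -0.07 and 0.04 that differed in sign without passing.

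The rule for named genes took the passing probes of 1 gene, of which there were 0, and up to 3 members with the smallest p of each testable fixed list, which gave PRK, PSBY and PSAN. A second rule, added after the data were seen, took the 10 genes per direction with the smallest p among probes of 1 gene that were above 0 in all 12 samples and had 1 direction in all 3 couples. Gene lists were tested with limma's camera (preset correlation 0.01), with an estimated correlation and with fry, where at least 3 members were measured. A further 9 lists were assembled after the gene names were known. Differences between groups in values per sample were tested with exact permutation tests over 924 assignments of the 12 samples and, added after the data were seen, over 20 that keep couples whole.

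Samples with the same replicate number deviated together from their group means: the 6 correlations across probes lay between 0.292 and 0.568, and each sample's best match in the other group bore its own number in 6 of 6 cases both ways. By Spearman's correlation of the values this held for 4 of 6 both ways, not for uninfected 3 and 4 or mildew 5 and 6. The labels do not say what a number marks, so the pairing rests on the values. Within a group the best match by deviations was the other number of 1 and 2, 3 and 4, or 5 and 6 for all 12 samples. Mildew 3 and 4 were the weakest couple, with an r of deviations of -0.0579, and by Spearman's correlation each was nearer to another mildew sample. Deviations from a shared group mean push correlations within a group below 0, so the sign of such an r alone says little. These couples were used as a block, as averages and as units to leave out, all chosen after the data were seen. The alternatives set out beforehand were the values as deposited, median centring, cyclic loess, a filter on dim probes, an offset, zeros as missing, trended robust moderation, array weights, the replicate number as a fixed block or random effect, leaving out each sample, stricter thresholds and other set tests. A floor at the 25th percentile was added.

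The fit was tested on simulated data of 12 independent samples with 200 changed probes among 3439 in 20 runs. The changed probes were drawn only from those brighter than the median probe. Of these, the fit recovered 64.0% of 2-fold and 93.5% of 4-fold changes, and 4.71% of the calls were false. Recovery among dimmer probes was not simulated, nor were recovery and false calls in samples correlated within couples. Those shares therefore hold for independent samples only, which these may not be. Simulated data of the same size with no effect and a correlation of 0.520 within couples gave a median of 0 calls without a block and with the replicate number as a block, with at most 3 in each. The closer resemblance of same-numbered samples across groups was not simulated.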

Results

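Plants of Arabidopsis thaliana ecotype Columbia were compared 2 days after mildew infection with plants that were not infected, to ask which transcripts differ in abundance early in the infection. Total RNA of 12 samples was measured on a microarray, 6 samples per group, and 3439 probes were read in each sample. The labels name neither the tissue nor the mildew species. The mean intensity of a sample lay between 0.928 and 1.04 in the deposited units, and values ran from 0 to a ceiling of 100. Median intensities lay between 0.242 and 0.596, and between 180 and 436 probes of a sample were listed at 0. The number of arrays limits the precision of every value below.

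In the infected plants the probe for ATSPS4F, a sucrose phosphate synthase, was 2.12-fold brighter than in the uninfected plants (log2 difference 1.09 ± 0.24, SE, n = 6 per group). Probes for the plastid ribosomal proteins S10 (AT3G13120) and L17 (AT3G54210) were 2.05-fold and 1.47-fold brighter, with log2 differences of 1.03 ± 0.21 and 0.56 ± 0.13. CCL, a light-regulated and clock-controlled transcript, stood at 0.448 of its uninfected level (log2 difference -1.16 ± 0.30), and CML30, a calmodulin-like calcium sensor, at 0.550 (-0.86 ± 0.24). These sizes depend on the scaling: as deposited the log2 differences of AT3G13120 and AT3G54210 were 0.35 and 0.18, and after median centring those of ATSPS4F, AT3G54210, CCL and CML30 were 1.70, 0.85, -0.39 and -0.47. Without numbers 1 and 2 of both groups CCL and CML30 had -0.54 and -0.47. The 5 genes were picked after the data had been seen, out of 10 per direction with a small p and the same direction in all 3 couples of replicate numbers. They were not those with the smallest p: AT3G56290, AT1G31790 and AT1G73470 ranked before the higher ones, and AT3G50180 and AT3G19120 before CCL and CML30. So ATSPS4F, AT3G13120 and AT3G54210 being higher in 6 of 6 same-number pairs, and CCL and CML30 in 0 of 6, is not independent evidence. None of these 5 genes passed limma's test over all 3439 probes, with adjusted p from 0.0621 for AT3G13120 to 0.128 for CML30 and CCL. Within a group, numbers 1 and 2, 3 and 4, and 5 and 6 were nearest in their deviations from the group mean, weakly so for mildew 3 and 4 (r = -0.0579 across probes). With these couples as a block of the 12 samples, all 5 passed, with adjusted p of 0.00314 for ATSPS4F, 0.0170 for AT3G13120, 0.00792 for AT3G54210, 0.0470 for CCL and 0.0353 for CML30. None of the 5 passed once each couple was averaged to 1 sample (adjusted p = 0.610 for each with the couple as a block) or once the couple within a group was a random effect (adjusted p from 0.426 to 0.591). These fits with couples were chosen after the data had been seen too, and picking genes for 1 direction in all 3 couples favours the fit with the block.

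Over the whole array, 6 probes rose and 0 fell in mildew at an adjusted p under 0.05 (limma, no block), while 524 probes had an unadjusted p under 0.05 against 171.95 expected by chance. That expectation takes the 12 samples as independent, which the couples make doubtful. With each couple averaged to 1 sample, 125 probes had an unadjusted p under 0.05 in limma, fewer than 171.95, and 243 with the couple as a block. The log2 differences of the 6 lay between 1.05 and 3.95, and each of the 6 was higher in 6 of 6 same-number pairs, which their selection on these samples nearly fixes. As deposited, 4 of the 6 passed, and the mean of probe 3776 (log2 difference 1.14) went only from 0.226 to 0.275. None of the 6 probes is tied to 1 gene by the platform annotation: 5 are not listed there and 1 is listed with several genes. Probe 534 (log2 difference 3.95 ± 0.48, adjusted p = 0.0120) is very dim, with deposited means of 0.0135 ± 0.0143 without mildew and 0.0515 ± 0.0361 with it (SD, n = 6) and 1 uninfected sample at 0. Its size and its rank depend on the normalization and the floor: the log2 difference of probe 534 was 1.34 as deposited (adjusted p = 0.0835) and 1.37 with an offset (adjusted p = 0.00704), and all 12 samples lay at the floor when it was set at the 25th percentile. Probe 2791 had 1.71 ± 0.24 (adjusted p = 0.0129), and its deposited mean went from 0.557 ± 0.0574 to 1.36 ± 0.342 (SD, n = 6).

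With the couple of numbers as a block, 348 probes passed, 210 higher and 138 lower in mildew, including all 6 of those above. Among probes of 1 gene, 33 rose and 23 fell in that fit. Simulated data without any effect, with a correlation of 0.520 within couples, gave a median of 9.5 calls and at most 37 in 20 runs of that fit. They lacked the closer resemblance of same-numbered samples across groups, so they match these data only in part. With the replicate number as a block, 0 probes passed (smallest adjusted p 0.0625, 752 at an unadjusted p under 0.05), and with each couple averaged to 1 sample, 3 against 3, 0 passed in limma (125 unadjusted), or 0 with the couple as a block as well (243 unadjusted). Without normalization between samples the calls leaned the other way, with 20 higher and 335 lower, and the median probe differed by -0.62 on the log2 scale. After median centring 87 were higher and 15 lower, and after cyclic loess 17 and 5.

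The labels do not say that the samples came from separate plants, so p-values measure only the spread between these samples, which may be technical, and the independent samples may number 3 per group. Leaving out single samples moved the count of passing probes from 6 to 19 without uninfected sample 4, to 16 without mildew sample 4 and to 11 without mildew sample 3. Leaving out any other single sample gave between 4 and 6, mostly fewer than 6. Leaving out couples gave 4 without 1 and 2 (1 of the 6 among them), 230 without 3 and 4 (all 6) and 2 without 5 and 6 (0 of the 6).

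**Figure D1:**
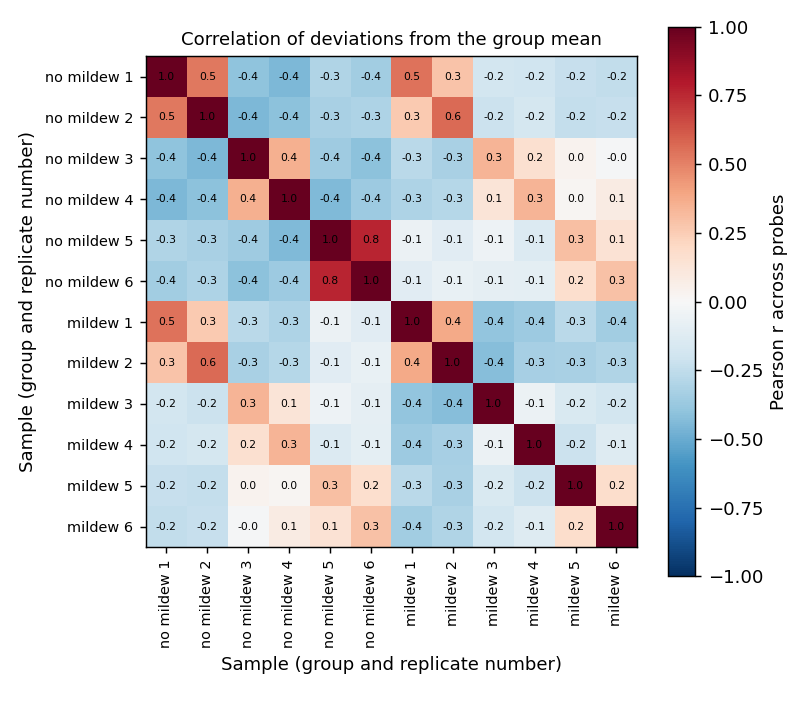
Pearson correlation across 3439 probes of each sample's deviations from its group mean, for all 12 samples on both axes, with red above and blue below 0. Samples with the same replicate number in the other group correlate at 0.292 to 0.568, and samples of the same group from other couples at -0.450 to -0.129. Taking deviations from the group mean itself pushes correlations within a group below 0, so that negative sign is not an observation. Spearman's correlation of the values of these same-group pairs lay between 0.745 and 0.870.

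A set of 10 genes in each direction was picked after the data had been seen, as those with the smallest p among probes of 1 gene that were above 0 in all 12 samples and differed the same way in all 3 couples. Since they were chosen from these samples, their shared direction is not independent evidence. The gene nearest to the threshold was AT3G56290 (log2 difference 1.17 ± 0.22, adjusted p = 0.0606). It was followed among the brighter probes in mildew by AT1G31790 (0.67 ± 0.14), AT1G73470 (1.37 ± 0.28), AT3G13120, ATSPS4F and AT3G54210. The others were AT5G06410 (0.70), AT2G25640 (0.71), AT3G27180 (0.86) and AT5G27860, a dim probe with deposited means of 0.0419 and 0.0769. The log2 difference of AT5G27860, 2.63 ± 0.62, was 1.02 as deposited and 1.21 with an offset, and vanished with the floor at the 25th percentile, where all 12 samples lay at the floor. All 10 passed with the couple as a block, a fit that their selection for 1 direction in all 3 couples favours. On couple means 0 of them passed. The direction of AT5G06410 and AT3G27180 depended on the scaling: their log2 differences were -0.15 and -0.07 as deposited, and 0.52 and 0.60 after median centring. As deposited, those of AT2G25640, AT1G31790, AT3G56290 and AT1G73470 were 0.08, 0.22, 0.59 and 0.85.

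Among the 10 genes with dimmer probes in mildew, AT3G50180 (-1.06 ± 0.22) and AT3G19120 (-1.06 ± 0.25) had the smallest p. AT3G19120 went from a deposited mean of 1.23 ± 0.481 to 0.415 ± 0.108, and AT3G50180 from 1.71 ± 0.488 to 0.692 ± 0.140 (SD, n = 6). The others besides CCL and CML30 were AT5G40030 (-0.58), AT2G37580 (-0.65), AT5G34870 (-0.46), AT1G50770 (-0.81), AT1G74070 (-0.64) and AT2G27290 (-0.82). As deposited, AT5G40030, AT2G37580, AT5G34870, AT1G50770 and AT1G74070 had between -1.21 and -1.07, and after median centring between -0.54 and -0.40, while AT3G50180 had -0.61 and AT3G19120 -0.83 after median centring. AT2G27290 was the brightest of these genes, with deposited means of 35.5 ± 1.76 and 27.3 ± 10.8. It was the single gene of the 10 that missed the threshold with the couple as a block (adjusted p = 0.0546), a fit that their selection favours. On couple means 0 of the 10 passed. After median centring the log2 difference of AT2G27290 turned to 0.17. CCL differed most in numbers 1 and 2 (-2.43) and less in 3 and 4 (-0.44) and 5 and 6 (-0.60).

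**Figure D2:**
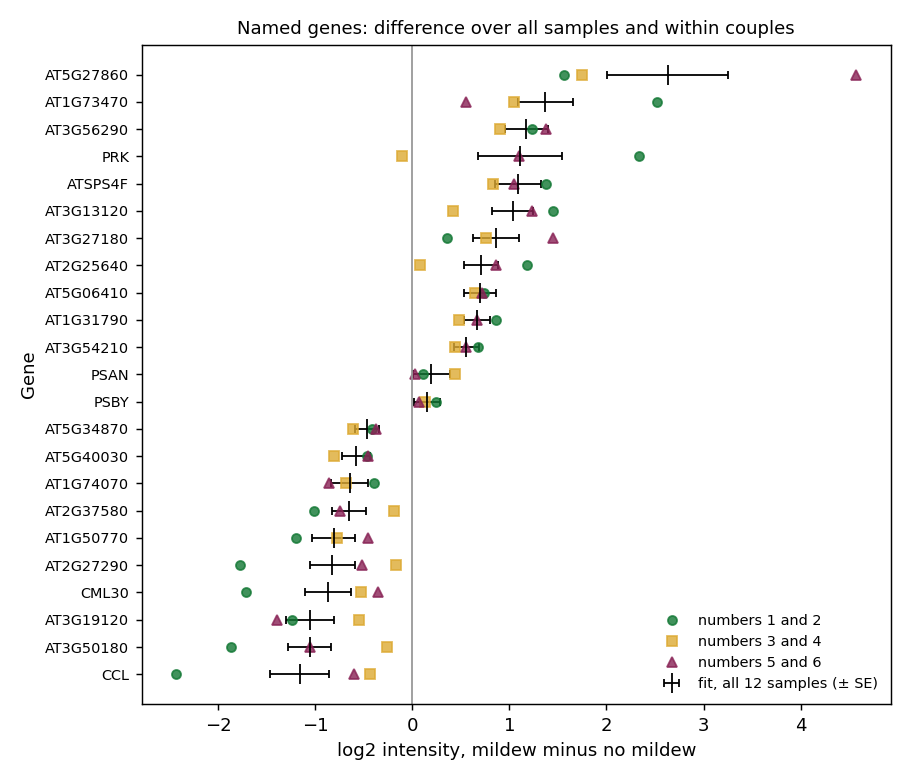
Log2 intensity in mildew minus no mildew (horizontal axis) for each of 23 named genes (vertical axis). Black marks give the difference over all 12 samples with its standard error, and coloured points the differences within the couples of replicate numbers. PRK is the single gene whose couples lie on both sides of 0, from -0.11 to 2.33. All genes but PRK, PSBY and PSAN were picked for 1 direction in all 3 couples, so only these could lie on both sides.

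Photosynthesis was the single gene list fixed before the data were examined that could be tested, through 6 of its 57 members. Of these 6, 3 were higher and 3 lower in mildew, which became 5 higher and 1 lower both as deposited and after median centring, and 0 passed, over all probes or adjusted over the list alone. PRK, the Calvin cycle enzyme phosphoribulokinase, had a log2 difference of 1.11 ± 0.43 (adjusted p = 0.243), carried by numbers 1 and 2 (2.33) and 5 and 6 (1.10). The difference of PRK was 0.63 as deposited, 1.30 after median centring and 0.54 without numbers 1 and 2. The photosystem subunits PSAN and PSBY had log2 differences of 0.20 ± 0.19 and 0.15 ± 0.13 (0.89 and 0.80 after median centring), and LHB1B2, a light-harvesting chlorophyll protein, -0.23 ± 0.30, which turned to 0.03 as deposited and 0.70 after median centring. The median of the 6 was -0.01 and their mean -0.03, while camera placed the list up relative to the other probes (p = 0.607, and p = 0.609 with an estimated correlation). Camera in limma placed the same list up with an adjusted p of 0.000436 in the values as deposited, relative to the lower median of all probes there, and with an adjusted p of 0.0200 after median centring. The other 24 fixed lists, among them pathogenesis-related proteins, salicylic acid and jasmonate signalling, camalexin synthesis and markers of other cell types, had 0 members on probes of 1 gene, so PR1, PR2, PR5, PDF1.2 and ICS1 were not analysed here.

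The infected samples also differed in the shape of their intensity distribution. The median probe intensity was 0.304 ± 0.0556 with mildew and 0.495 ± 0.134 without it (SD, n = 6, exact two-sided permutation p = 0.0216, adjusted p = 0.0216 over 5 measures). The count and the percent of probes at 0 both belong to these measures though they are the same quantity. This somewhat lowers the adjusted p of the zeros, the brightest 1% and the ceiling. Probes listed at 0 made up 9.31% ± 2.09 of the array with mildew and 5.80% ± 0.726 without (SD, n = 6, exact permutation p = 0.00216, adjusted p = 0.0036). The brightest 1% of probes held 36.7% ± 1.44 of the summed intensity with mildew and 26.2% ± 5.23 without (SD, n = 6, exact permutation p = 0.00216, adjusted p = 0.0036), and an average of 2.67 ± 1.37 probes against 0.333 ± 0.516 lay at the ceiling (SD, n = 6, exact permutation p = 0.0130, adjusted p = 0.0162). Those p-values take the 12 samples as exchangeable, which the couples are not: with couples kept whole, 20 assignments allow no two-sided exact permutation p under 0.1, and p was 0.1 for the zeros and the brightest 1% and 0.2 for the median and the ceiling. Each of these differences had the same direction in 3 of 3 couples; the median fell short of the uninfected one by 0.0715 units in numbers 3 and 4 and by 0.281 in 5 and 6.

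**Figure D3:**
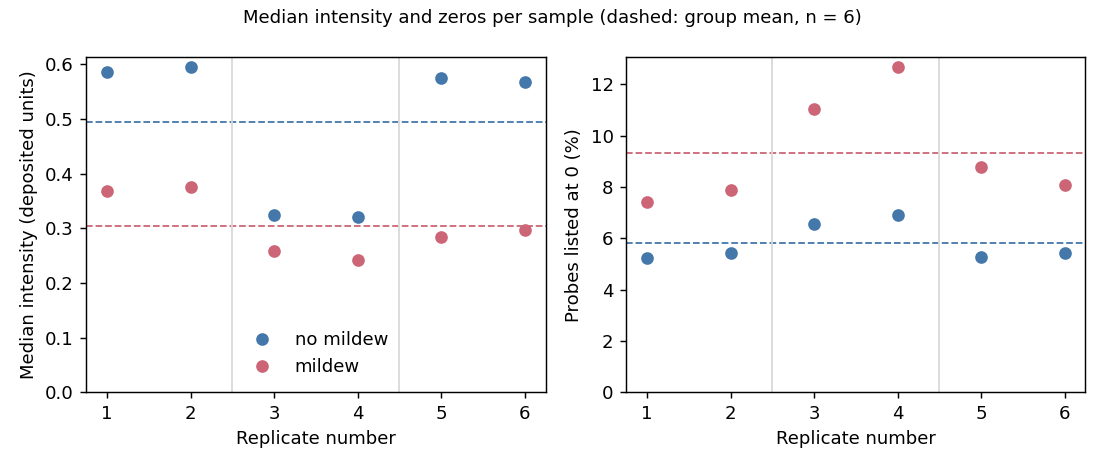
Median intensity in deposited units (left) and percent of probes listed at 0 (right) for each sample by replicate number; dashed lines are group means (n = 6) and grey lines part the couples. Uninfected samples 3 and 4, at 0.324 and 0.320, lie below the other uninfected samples, and every mildew sample has more zeros than every uninfected one.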

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

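The fits with couples of numbers, those lacking a couple and the floor at the 25th percentile were chosen after the data were seen. The 6 passing probes, all higher, became 355 as deposited (20 higher, 335 lower), 102 after median centring (87, 15), 22 with cyclic loess (17, 5), 27 with dim probes left out (22, 5), 34 with an offset (26, 8), 37 with zeros as missing (32, 5), 35 with trended robust moderation (27, 8) and 286 with array weights (165, 121), whose estimation stopped short of its tolerance. The replicate block gave 0 (0 higher, 0 lower), the replicate block with cyclic loess 21 (19, 2) and the replicate number as a random effect 191 (125, 66). The couple as a block gave 348 (210, 138), couple means 3 against 3 gave 0 (0, 0) without and 0 (0, 0) with the couple as a block, and the couple within a group as a random effect 0 (0, 0; 226 unadjusted). The floor at the 25th percentile gave 50 (33, 17). Without couple 1 and 2 there were 4 (2, 2), of which 1 was among the 6, without couple 3 and 4 there were 230 (130, 100), with all 6, and without couple 5 and 6 there were 2 (0, 2), with 0. At an adjusted p under 0.01, 0 probes passed (0 higher), and a fold limit of 1.5 kept 6. Leaving out 1 sample gave 4 to 19 passing probes, 4 to 17 higher and 0 to 3 lower. The number of fixed lists that differed, 0, became 1 as deposited (limma's camera, adjusted p = 0.000436) and 1 after median centring (adjusted p = 0.0200) and stayed 0 under the other alternatives run. Both calls were of the photosynthesis list, and they may follow the brightness of its members, as said above. Lists were not run with zeros as missing, array weights or random effects, and the mean of all probes of a gene moved nothing, since no list member had several probes.

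For the 23 named genes, 734 alternative values were computed: 579 kept direction and side of the threshold, 152 passed it and 3 turned direction (no call could be lost, since 0 of the genes passed at first), namely AT5G06410 (-0.15) and AT3G27180 (-0.0693) as deposited and AT2G27290 (0.17) after median centring. AT5G27860 has no value with the floor at the 25th percentile, where all 12 samples lay at the floor, nor with dim probes left out. The replicate block changed no call of a named gene. In exact permutation tests 21 of the 23 had an adjusted p under 0.05, adjusted over these 23 genes alone, not over all probes. These 21 are counted among the 152, although the other values there were adjusted over the probes tested. Most of the 23 genes were picked on these samples, and the permutation tests take samples of a couple as exchangeable. The cause of these changes was not tested. Dim probes limit the precision: the lowest values stand at the floor, and what lay under it has no order.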

Other observations

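The tests on couples of numbers, their splits and the 9 further gene lists were chosen after the data were seen, and those on chance splits and on median intensity before their results were.

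Genes of plastid and mitochondrial gene expression, with chaperonins, were the added list with the most members past a threshold. Of 11 measured, 7 were higher and 4 lower in mildew (2 and 9 as deposited, where the median of all probes was -0.62), 2 passed when adjusted over the list alone (AT3G13120 and AT3G54210) and 0 over all probes. The list moved up on balance in fry (adjusted p = 0.0181 over 9 lists), yet did not stand apart from other probes in camera (adjusted p = 0.772, and adjusted p = 0.887 with an estimated correlation). Fry took the 12 samples as independent and was not run with couples. In camera with the couple as a block the adjusted p was 0.867. Both ribosomal proteins were also among the genes picked for their small p, so the list is not independent of them. In the list of carbon fixation and carbohydrate genes, ATSPS4F passed over the list alone, while the Calvin cycle enzyme SBPASE had -1.23 ± 1.26. The value of SBPASE was carried by couple 1 and 2 (-3.39, against -0.48 and 0.17 in the other couples), with 1 mildew sample at 0. The median of the carbon fixation and carbohydrate list was -0.19, its mean 0.10 and its test up. In the list of calcium, hormone and stress signalling CML30 passed over the list alone, and XERICO, a RING-type gene linked to abscisic acid, had -0.63 ± 0.25. That list's median was 0.03, its mean -0.02 and its test down.

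The other 6 added lists had 0 members past either threshold. Redox and detoxification genes had a median of -0.35 (3 higher, 5 lower), amino acid, sulphate, nucleotide and vitamin synthesis 0.32 (4 higher, 3 lower; the middle value is that of UPP, listed at 0 in all 12 samples, and comes from the normalization of zeros), floral and reproductive regulators 0.17 (5 higher, 2 lower), and photosystem and related complexes 0.03 (6 higher, 5 lower). Tetrapyrrole and carotenoid genes had a median of -0.01 and a mean of 0.01 (2 higher, 3 lower), and cell wall polysaccharide enzymes a median of -0.09 with a test that pointed up (1 higher, 4 lower), and a median of -0.63 as deposited and -0.62 after median centring relative to that of all probes. As deposited, 0 genes were higher in the floral, calcium and hormone, tetrapyrrole, and amino acid lists (7, 11, 5 and 6 lower) and 1 in the redox list (7 lower). After median centring 9 of 11 photosystem, 4 of 5 carbon fixation and 3 of 5 tetrapyrrole genes were higher, 3 of the amino acid list were higher and 3 lower, and 5 of the calcium and hormone list were higher and 6 lower. Camera's adjusted p over the 9 lists lay between 0.772 and 0.983.

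AT3G09850, singled out after its values were seen, reached the ceiling of 100 in mildew samples 1 and 2 against a mean of 9.09 in uninfected samples 1 and 2, while the other 4 mildew samples lay between 22.0 and 24.8 and the other 4 uninfected ones between 19.6 and 25.1. Among the 1719 probes of the brighter part of the array, 21 were at least 4-fold higher and 18 at least 4-fold lower in mildew within couple 1 and 2, against 1 and 7 within couple 3 and 4, and 5 and 3 within couple 5 and 6. Over all probes, 1142 (33.2%) differed in the same direction in all 3 couples, where 25% would by chance if probes and couples were independent, and the differences of any couple correlated with those of another at r between 0.144 and 0.247 across probes, which are not independent replicates.

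The count of 6 passing probes was set against other splits of the 12 samples. Of 100 splits drawn from 462, 1 gave as many, the real one, and the highest other of those drawn gave 4, which would exclude chance only if the 12 samples were exchangeable. Of the 32 splits that part all 6 same-number pairs, the highest other gave 1. Samples of a couple are not exchangeable, so chance is not excluded by these draws, and of the 10 splits that keep couples whole 4 gave at least 6, the highest 745, for the 6 samples with the highest median intensities (couple 1 and 2 of both groups and uninfected couple 5 and 6), which points to a structure of the samples, while 10 splits are too few for a share under 0.05. With the couple as a block, the real split gave 348 and the other 3 that can be made gave 20 to 27, again too few splits for such a share.

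The lower median and the more frequent zeros in mildew were weighed against the making of the table. The median log2 difference as deposited was -0.57 ± 0.14 (SE over 3 couples). If a few bright probes took a larger share of each mildew column, scaling without the brightest 1% would bring it near 0, and it became -0.265 ± 0.0827. By couple it was -0.172 in 1 and 2, -0.193 in 3 and 4 and -0.430 in 5 and 6, so the prediction was not met. A larger share of the brightest 1% stays open as an account of a part of the difference, not of the whole. If a constant background had been subtracted more strongly in mildew, probes between the 90th and 99th percentile of intensity should be near 0 and dim ones low, and they had -0.0768 ± 0.138 against -0.80 ± 0.22 between the 25th and 50th percentile. By couple the brighter probes had -0.343 in 1 and 2, -0.00793 in 3 and 4 and 0.120 in 5 and 6. Their mean near 0 thus joins opposite signs, and couple 1 and 2 alone does not meet the prediction. Such a subtraction therefore only stays open. An effect of the infection on the RNA stays open too and was not tested.

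The resemblance of numbers 1 and 2, 3 and 4, and 5 and 6 within a group (median r of deviations 0.367, from -0.0579 for mildew 3 and 4, which do not stand out by Spearman's correlation, to 0.761) was weighed against 3 ways the arrays could have been read. A mildew and an uninfected sample of the same couple but of other numbers had a lowest r of 0.125, as 3 occasions shared by both groups would give. The odd minus even differences of a couple correlated between the groups with a lowest r of 0.236, as shared arrays or positions for same-numbered samples would give. This largely restates the resemblance of same-numbered samples already seen, so it is no separate test of how the arrays were read. Between couples the odd minus even differences had a median r of 0.0734, which leaves open whether each couple may be a pair of readings of a single hybridisation at fixed positions. No biological explanation was tested, since the labels give no group that follows the numbers.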
